A study of Drosophila melanogaster with 36 samples.

How the data were processed

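The series holds 36 RNA-seq libraries of LNv neurons from female Drosophila melanogaster. LNv neurons are the ventral lateral clock neurons of the fly brain, most of which make the neuropeptide PDF. They were marked with membrane-bound GFP driven by Pdf-Gal4, and brains were dissected and the cells sorted by fluorescence, per the labels' protocols. RNA from the sorted cells was copied into cDNA, amplified with T7 RNA polymerase and copied into cDNA again before sequencing, per the labels' protocols. Flies were kept on food with 1.5x sucrose and yeast at 25 °C (HC25), on food with 0.5x sucrose and yeast at 25 °C (LC25), or on food with 1.5x sucrose and yeast at 18 °C (HC18). The pairing of each code with a food and a temperature was read from the code itself and the design text. Each condition was sampled at 12 zeitgeber times (ZT, hours on the day's light schedule) from ZT02 to ZT24 in steps of 2 h, with 1 library per time point and condition.

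The deposited abundance table gives TPM (length-normalized transcript abundance, scaled to a fixed total) per transcript and library, and the submitters' processing notes name kallisto. Its version, the transcript set and the genome build are not given in the sources used here. Deposited TPM values of each library sum to 1000000 within rounding, so they carry no sequencing depth: the depth of each library is unknown, and no counting interval or detection limit is given. TPM are shares, so a gene that takes a larger part of a library lowers the values of all others. The libraries had between 10492 and 13182 genes with TPM above 0, and between 7938 and 10547 genes with TPM of 1 or more. The authors also deposited results of BooteJTK, a rank test for rhythms, for the libraries at 25 °C and for all 36 libraries. These tables hold the authors' mean TPM, a score (headed TauMean), a mean peak phase, p-values from a gamma fit and their Benjamini-Hochberg adjustment, per the file headers. The filter on genes behind them is not given in the sources used here. A further deposited table holds the gene sums of the same TPM and was not used.

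Transcripts were assigned to genes with the Ensembl release 115 annotation of BDGP6.54, which was used for names only. Of 30485 transcripts, 30246 matched, and the 239 others held a mean of 0.139% of the TPM of a library. TPM were summed over the transcripts of a gene. All values were tested as log2(TPM + 1), for the 8649 genes with a mean TPM of at least 1 over the 36 libraries, so that a fold change is on that scale and understates the change of low genes. The 2 reporter sequences in the table were kept out of these tests. Genes with near-identical copies, such as Hsp70Ab and the lysozyme genes, and genes that overlap another gene are uncertain, because the quantification can divide reads among them and no source used here says whether strand was used.

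Rhythms were tested with limma 3.58.1 (R 4.3.3; lmFit and eBayes with a trend) as 24 h cosine regressions. A fit with separate means, cosine and sine terms per condition gave the rhythm of each condition and the differences between conditions. A fit with separate means and common cosine and sine terms gave the shared rhythm over the 3 conditions. Amplitudes are on the log2 scale from mean to peak with their standard errors, and folds of rhythms are peak to trough of the fitted curve. Levels were compared in a fit with condition and time point as factors, so that each difference rests on 12 time-matched differences. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p below 0.05 were called. Because each time point and condition has 1 library and the labels do not say whether libraries came from separate animals or pools, p-values measure only the spread between these libraries around the fitted curve, which may be technical.

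The designs, alternatives, 26 gene lists and the rule for named genes were fixed before the data were examined. The rule named the 10 genes of smallest p per rhythm test and, for levels, the 10 higher and 10 lower genes of largest change, with a mean TPM of at least 10 and, for levels, the same direction in at least 10 of the 12 pairs. All 8 core clock genes, Pdf and Stip1 (also called Hop), and up to 4 members of each list with the smallest p were also named. The lists covered the core clock, clock kinases and modifiers, LNv markers and neuropeptides, neuropeptide processing and release, membrane excitability, activity-regulated genes, chaperones and co-chaperones, the unfolded protein response, the proteasome, autophagy, cytosolic ribosomal proteins, the respiratory chain, glycolysis and trehalose metabolism, insulin and TOR signalling, cold-induced genes, antimicrobial peptides, oxidative stress defence, and 9 groups of markers of other cells (glia, photoreceptors, fat body, haemocytes, muscle, Kenyon cells, monoaminergic neurons, transmitter synthesis of other neurons and other clock neurons). A list of lysozymes was added after the data were seen. Some genes stand in more than 1 list: sNPF is an LNv marker and a Kenyon cell gene, and Dh31 is an LNv neuropeptide and a gene of other clock neurons. Listed symbols were matched to current ones (E75 is Eip75B). The gene meng stands in the activity-regulated list under an older symbol.

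List levels were tested with camera of limma (preset correlation 0.01), with camera under an estimated correlation and with fry, each adjusted over the 26 lists. List rhythms were tested by the median F of the members against 100 random orders of the time points within conditions. The smallest p this can give is 0.0099, or 0.0161 after adjustment over the lists for the shared rhythm. Alternatives changed the pseudocount, the filter on low TPM, the scaling (median ratio or quantile normalization), the library weights, the time term, the libraries included, the summing of transcripts and the rhythm test (a rank test over 12 phases). Fits without libraries that stood apart, and a fit with log2 TPM of fmt as a covariate, were chosen after the data were seen. The main rhythm and level fits were tested on simulated data made from the real genes' means and residual spreads, with 100 changed genes per size. At a 4-fold peak-to-trough rhythm, 83% of changed genes were recovered in HC25, 84% in LC25, 79% in HC18 and 97% for the shared rhythm. At that size of difference in rhythm, 63% were recovered for LC25 and 47% for HC18 against HC25. At a 2-fold level difference, 79% were recovered for LC25 and 87% for HC18, and at a 1.41-fold difference 27% for each.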

Results

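Transcript levels were measured in sorted LNv clock neurons every 2 h over 1 day in flies on rich food at 25 °C (HC25), on poorer food at 25 °C (LC25) and on rich food at 18 °C (HC18), with 12 libraries in each condition. The study's stated aim was to find transcripts that cycle over the day in these neurons under each food and temperature condition. Values are TPM, so the sequencing depth behind them is unknown. A single library stood for each time point and condition.

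The neuropeptide gene Pdf, the marker of LNv neurons, had the highest mean level and took 23.7% ± 4.19 of TPM (SD, n = 36 libraries). Its lowest share was 7.68%, in HC25 at ZT06. Next came fmt, with 34348 ± 25459 TPM (SD, n = 36), and trol, with 22486 ± 9020 TPM (SD, n = 36). Mitochondrially encoded transcripts took 14.04% ± 2.56 of TPM in HC25 and 13.9% ± 3.06 in LC25, but 8.30% ± 3.03 in HC18 (SD, n = 12 each). Cytosolic ribosomal protein transcripts took 11.5% ± 1.91 in HC25, 11.3% ± 1.59 in LC25 and 14.7% ± 2.04 in HC18 (SD, n = 12 each). In 4 HC18 libraries fmt was far lower than in the rest: 346 TPM at ZT06, 1603 TPM at ZT08, 121 TPM at ZT10 and 195 TPM at ZT22, against at least 6458 TPM in every other library. These 4 held 3.08 to 7.05% of mitochondrially encoded transcripts (mean 5.08%) and 15.7 to 19.1% of ribosomal protein transcripts (mean 16.9%), and the other 8 HC18 libraries had means of 9.91% ± 2.07 and 13.6% ± 1.17 (SD, n = 8). The HC25 library of ZT06 had a median Spearman correlation of 0.837 with the others across genes. In it CG45080 (86205 TPM), whe (67016 TPM) and CG34212 (43617 TPM) stood beside Pdf, and these 3 genes reached at most 175 TPM in the other 35 libraries. It also held 18572 TPM of the lysozyme gene LysP.

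**Figure D1:**
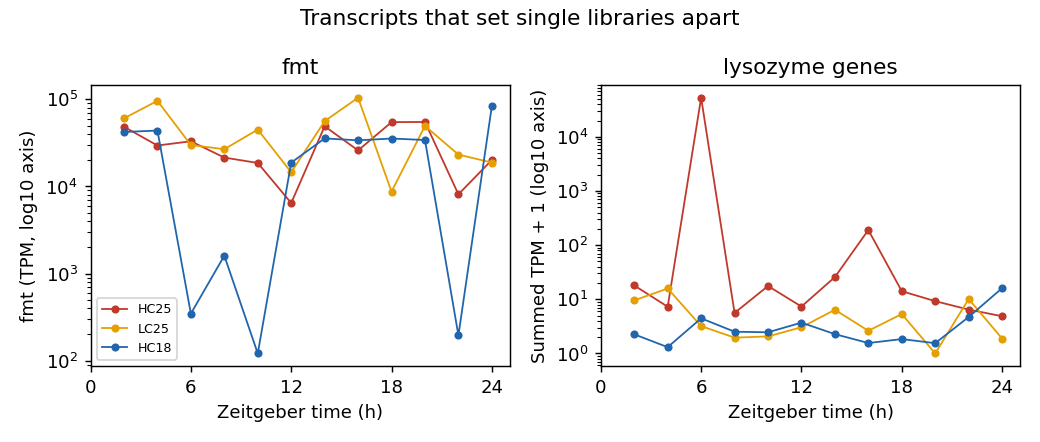
Left, fmt in TPM (log10 axis) and right, the summed TPM + 1 of the lysozyme genes (log10 axis), both against zeitgeber time in hours, with 1 point per library and 1 line per condition. The 4 HC18 libraries low in fmt (121 to 1603 TPM) and the HC25 library of ZT06 (52696 TPM of lysozyme transcripts) stand apart.

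Transcripts of the core clock cycled with large amplitude in LNv neurons over the 3 conditions. Peak times here and below are those of the fitted cosine. vri, a repressor of Clk transcription, varied 89.6-fold between trough and peak (log2 amplitude 3.24 ± 0.184 SE, n = 36 libraries), with a peak at ZT14.9 (limma adjusted p = 2.52e-16). The gene tim, whose protein partners PER, varied 14.2-fold with a peak at ZT16 (amplitude 1.91 ± 0.107 SE, adjusted p = 1.78e-16). Pdp1, an activator of Clk transcription, varied 12.6-fold with a peak at ZT16.5 (1.83 ± 0.105 SE, adjusted p = 2.65e-16), and per varied 5.56-fold with a peak at ZT17.6 (1.24 ± 0.105 SE, adjusted p = 2.07e-11). The highest measured values of tim and Pdp1 lay at ZT14 in each condition, earlier than their fitted peaks. Clk, which encodes an activator of per and tim, ran opposite to them, with a peak at ZT2.80 and a 10.3-fold range (1.68 ± 0.137 SE, adjusted p = 5.5e-12). The transcriptional repressor gene cwo varied 1.89-fold (adjusted p = 1.96e-05) and cyc 1.44-fold (adjusted p = 0.0396; 0.0841 without the HC25 library of ZT06). The photoreceptor gene cry had a fitted 1.65-fold range and did not pass (adjusted p = 0.176). Of the 8 core clock genes 7 were rhythmic, also when adjusted over the list alone.

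**Figure D2:**
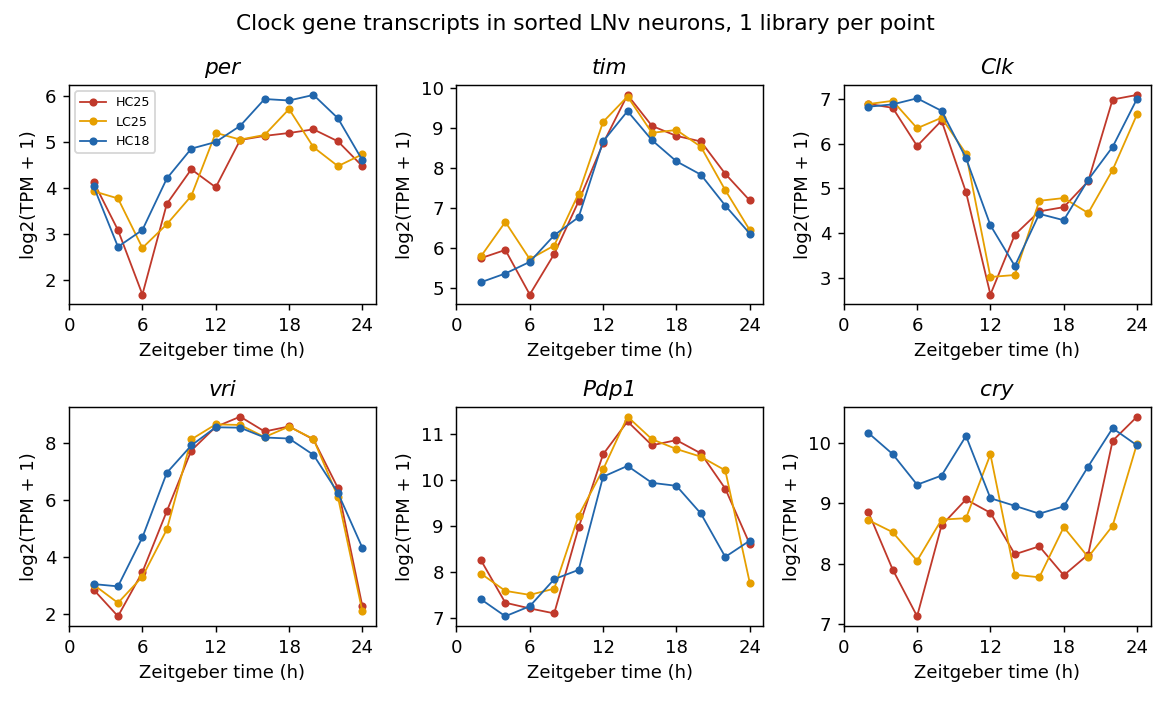
log2(TPM + 1) of per, tim, Clk, vri, Pdp1 and cry against zeitgeber time in hours, with 1 point per library and 1 line per condition; the vertical axes differ between panels. The fitted peak of vri over the 3 conditions lay at ZT14.9 and that of Clk at ZT2.80, and cry did not pass the rhythm test.

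Pdf itself showed no rhythm past the threshold, with a fitted 1.06-fold range (amplitude 0.04 ± 0.094 SE, limma adjusted p = 0.926). Receptors and peptides of these neurons did cycle. sNPF, a neuropeptide gene of LNv and other neurons, varied 30.5-fold with a peak at ZT21.4 (adjusted p = 6.06e-13). Dh31, a diuretic hormone and clock neuropeptide gene, varied 9.57-fold with a peak at ZT7.82 (adjusted p = 1.01e-13), and Pdfr, the PDF receptor gene, varied 10.4-fold with a peak at ZT15.8 (adjusted p = 5.24e-09). Fer2, a transcription factor gene, varied 2.17-fold with a peak at ZT7.61 (adjusted p = 0.00132). In all, 5 of 8 measured LNv markers and neuropeptides were rhythmic (5 adjusted over the list alone). Besides tim and vri, the 10 genes of smallest p were CG12290 (43.9-fold, peak ZT14.6), CG31183 (61.6-fold, ZT17.2), Cipc (16.6-fold, ZT17.7), Dyrk2 (17.2-fold, ZT3.07), CG13054 (16-fold, ZT15.9), CG34325 (58.2-fold, ZT4.41), DIP-gamma (9.95-fold, ZT7.78) and Nmdmc (65.0-fold, ZT6.11). The co-chaperone gene Stip1 varied 1.46-fold with a peak at ZT14.1 (0.27 ± 0.0687 SE, adjusted p = 0.00942), and its adjusted p was 0.130 after rescaling by the median ratio.

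Over the 3 conditions 2065 of the 8649 genes were rhythmic at an adjusted p below 0.05 in limma. Their peaks were unevenly spread over the day: 609 lay between ZT15 and ZT18, 350 between ZT12 and ZT15 and 319 between ZT18 and ZT21. A smaller group of 289 genes peaked between ZT6 and ZT9, and 76 genes peaked between ZT0 and ZT3. These peaks rest on TPM as deposited. They were not counted again after rescaling by the median ratio, which gave 1891 rhythmic genes.

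**Figure D3:**
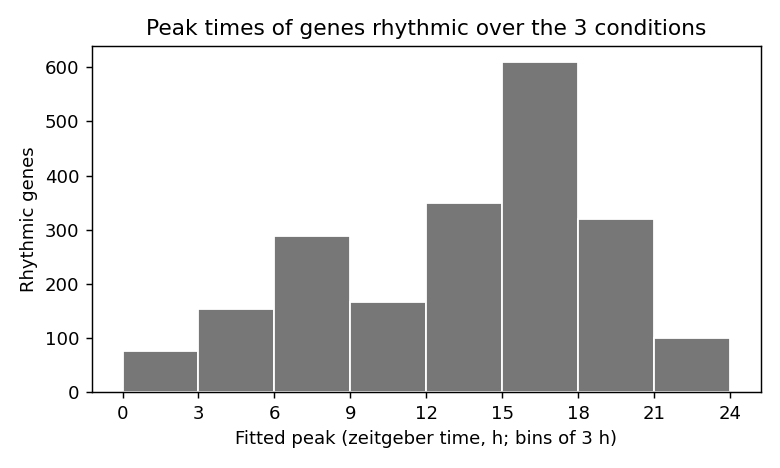
Number of rhythmic genes (vertical axis) by fitted peak in zeitgeber hours, in bins of 3 h, for the 2065 genes rhythmic over the 3 conditions. The bin from ZT15 to ZT18 held 609 genes and the bin from ZT0 to ZT3 held 76.

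The list counts here and below are to be read beside the 2065 rhythmic genes among all 8649. Whether a list exceeded that share was not tested, and several lists lie near or below it. In glycolysis and trehalose metabolism 11 of 16 measured genes were rhythmic (14 adjusted over the list alone), and 9 of them peaked between ZT6 and ZT12, among them Ldh, lactate dehydrogenase (9.92-fold, ZT7.56), Pgi (2.51-fold, ZT6.01) and the aldolase gene Ald1 (2.48-fold, ZT7.42). In insulin and TOR signalling 8 of 24 were rhythmic (9 adjusted over the list alone), led by Thor, a translational repressor (3.26-fold, ZT6.99), and by chrb (2.21-fold, ZT8.95) and scyl (1.60-fold, ZT8.68), which restrain TOR. In the mitochondrial respiratory chain 24 of 72 genes were rhythmic (26 adjusted over the list alone). Of these 24 genes, 22 peaked between ZT18 and ZT24, such as COX5B (1.48-fold, ZT22.6) and ND-MNLL (1.71-fold, ZT20.8). After rescaling by the median ratio 40 were rhythmic. The count was 17 without the 3 libraries least like the others (HC25 ZT06, HC25 ZT08 and HC18 ZT24), a fit that called 1947 of all genes. Of the chaperones and co-chaperones 13 of 30 were rhythmic (13 adjusted over the list alone; 8 after rescaling), 9 with peaks between ZT12 and ZT18, such as Hsp83 (1.52-fold, ZT15.5) and CCT2 (1.42-fold, ZT16.6). The unfolded protein response list had 5 of 17 rhythmic genes (5 adjusted over the list alone; 8 after rescaling), 4 of them with peaks between ZT6 and ZT12, such as Xbp1 (1.50-fold, ZT7.96) and crc (1.46-fold, ZT7.70), both transcription factor genes of that response. Of the activity-regulated genes 7 of 9 were rhythmic (7 adjusted over the list alone), 6 with peaks between ZT0 and ZT6, including meng (12.6-fold, ZT4.85), CrebA (2.45-fold, ZT4.60) and sr (2.53-fold, ZT1.45).

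Among genes of membrane excitability 7 of 21 were rhythmic (7 adjusted over the list alone; 4 without the 4 HC18 libraries low in fmt), with the potassium channel genes Irk1 (12.3-fold, ZT15.1), Shab (3.55-fold, ZT8.03) and SK (2.70-fold, ZT17.0) in front. In neuropeptide processing and release 4 of 18 were rhythmic (4 adjusted over the list alone), including the prohormone convertase gene amon (2.80-fold, ZT6.38) and Sytbeta (2.85-fold, ZT8.53). Of the clock kinases and modifiers 7 of 20 were rhythmic (10 adjusted over the list alone), including Usp8 (4.68-fold, ZT16.6), tyf, a cofactor of per translation (3.74-fold, ZT7.83), and dco, which encodes a kinase of PER (1.63-fold, ZT17.1). In oxidative stress defence 5 of 17 were rhythmic (6 adjusted over the list alone), including Gclc (3.83-fold, ZT20.7) and GstD1 (2.07-fold, ZT5.86). The proteasome had 4 of 32 rhythmic genes (2 adjusted over the list alone; 2 without the HC25 library of ZT06, and 1 after rescaling), led by Prosbeta2 (1.87-fold, ZT19.9). Of the antimicrobial peptides 2 of 7 were rhythmic (3 adjusted over the list alone), and of the cold-induced genes 1 of 8 (0 adjusted over the list alone). Of 17 autophagy genes and 76 cytosolic ribosomal protein genes 0 were rhythmic in limma, also adjusted over the list alone, and the smallest adjusted p values were 0.0509 for Atg5 and 0.133 for RpL5; 2 autophagy genes passed without the HC25 library of ZT06, and 2 without the 4 HC18 libraries low in fmt. The permutation test of the list's median F gave an adjusted p of 0.0161, the smallest it can give, for the core clock, kinases, LNv, peptide release, excitability, activity, chaperone, unfolded protein, proteasome, autophagy, glycolysis and insulin lists. It gave 0.0303 for the respiratory chain and 0.0429 for oxidative stress, and the antimicrobial (0.0542), cold-induced (0.347) and ribosomal protein (0.931) lists did not pass. The test sets a list against random orders of the time points, not against other genes. A pass therefore does not mark a list as more rhythmic than genes at large.

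Within single conditions the same clock genes cycled on rich food, on poorer food and at 18 °C. The range of vri was 134-fold in HC25, 121-fold in LC25 and 45.0-fold in HC18, and that of tim was 17.4-fold, 13-fold and 13.4-fold. Pdp1 varied 16.7-fold, 15-fold and 8.17-fold, Clk 11.4-fold, 10.1-fold and 10.6-fold, and per 5.58-fold, 4.58-fold and 6.83-fold. The largest limma adjusted p among these was 0.000363, for per in LC25 (n = 12 libraries per condition). The gene cwo passed in HC25 (adjusted p = 0.000406) but had adjusted p = 0.108 in LC25 and 0.37 in HC18, and Stip1 passed in none (0.337 in HC25, 0.146 in LC25, 0.71 in HC18). In all, 731 genes were rhythmic in HC25, 531 in LC25 and 477 in HC18. With each condition fitted alone the counts were 272, 436 and 621, so that HC25 had the most calls in the joint fit and the fewest alone. The joint fit without the HC25 library of ZT06 gave 548 in HC25, 708 in LC25 and 599 in HC18, so HC25 was then the lowest there too. Without the 4 HC18 libraries low in fmt, 270 genes were rhythmic in HC18.

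Of the rhythmic genes, 341 were called in both HC25 and LC25 (44.9 would be shared by independent lists), and 333 of these had peaks within 3 h of each other (median difference 0.71 h). HC25 and HC18 shared 327 genes (40.3 by independent lists), 316 of them within 3 h (median 1.02 h), and LC25 and HC18 shared 320 (29.3), 314 of them within 3 h (median 0.89 h). All 3 conditions shared 266 genes, against 2.48 by independent lists. With each condition fitted alone, so that the lists rest on separate libraries and separate estimates of the spread, the pairs shared 196, 215 and 313 genes (13.7, 19.5 and 31.3 by independent lists; Fisher's exact p = 4.52e-209, 1.21e-205 and 5.32e-289 across genes, which are not independent replicates).

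The first comparison asked whether poorer food changed rhythms at 25 °C. In the core clock, the vector difference between the LC25 and HC25 rhythms was 0.60 ± 0.332 SE on the log2 scale for Clk (limma adjusted p = 0.969), 0.43 ± 0.258 for tim (0.969), 0.36 ± 0.170 for cwo (0.969) and 0.08 ± 0.448 for vri (1). For Pdf it was 0.23 ± 0.248 (adjusted p = 1) and for Stip1 0.21 ± 0.173 (adjusted p = 0.994). In limma 0 of 8649 genes differed in rhythm after adjustment, and 355 had an unadjusted p below 0.05. That is less than the 0.05 share of genes that would pass without any difference. No other tool was run for this difference. Along the shared phase, the median amplitude of the 2065 rhythmic genes was 0.43 in HC25 and 0.40 in LC25, a median difference per gene of -0.03 (permutation p = 0.69 over 100 swaps of conditions within time points). Rhythm differences of 4-fold were recovered in 63% of simulated genes and smaller ones rarely (5% at 2-fold), so small differences were not detectable here.

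Against rich food, levels averaged over the day on poorer food gave no calls: Pdf was 1.13-fold (log2 0.17 ± 0.167 SE, higher in 7 of 12 pairs, limma adjusted p = 0.973) and Stip1 1.04-fold (log2 0.05 ± 0.118 SE, 9 of 12 pairs, adjusted p = 0.987). After adjustment 0 genes passed in limma, and 453 had an unadjusted p below 0.05. That is close to the 0.05 share of genes that would pass without any difference. As groups, the respiratory chain had a median log2 difference of -0.11 (0 of 72 members passed, 0 adjusted over the list alone), glycolysis and trehalose metabolism -0.13 (0 of 16, 0 adjusted over the list alone), glia markers -0.66 (0 of 8; 1 lower adjusted over the list alone), fat body markers -1.03 (0 of 5; 2 lower adjusted over the list alone) and neuropeptide processing and release 0.09 (0 of 18, 0 adjusted over the list alone). These lists passed in camera at the preset correlation, with adjusted p = 7.43e-05, 0.00327, 0.00327, 0.0117 and 0.0117. None passed with an estimated correlation (adjusted p = 0.885 for each with an estimated correlation), nor in fry. Without the HC25 library of ZT06, which held 973 TPM of glia and 111 TPM of fat body markers against medians of 245 and 23.04 TPM in the others, only the respiratory chain passed in camera (median -0.16, adjusted p = 1.62e-05). The HC25 library of ZT08 held more of both, 1983 TPM of glia and 260 TPM of fat body markers, and without the 3 libraries least like the others, which include both, the glia median was -0.12 and the fat body median -0.71 (adjusted p = 0.749 and 0.642). The other 21 lists did not pass in camera.

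The comparison of 18 °C with 25 °C, both on rich food, asked the same of temperature. Rhythm differences in the core clock were 0.61 ± 0.248 SE for Pdp1, 0.87 ± 0.448 for vri, 0.65 ± 0.332 for Clk, 0.55 ± 0.258 for tim and 0.40 ± 0.170 for cwo on the log2 scale, each with a limma adjusted p of 0.994. For Pdf the difference was 0.21 ± 0.248 and for Stip1 0.09 ± 0.173 (adjusted p = 0.994 for both). In limma 0 genes differed in rhythm after adjustment, and 316 had an unadjusted p below 0.05. This too is less than the 0.05 share of genes that would pass without any difference. No other tool was run for this difference. Without the HC25 library of ZT06, 5 genes passed. The median amplitude along the shared phase was 0.37 in HC18 against 0.43 in HC25, a median difference per gene of -0.05 (permutation p = 0.41 over 100 swaps).

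Levels over the day did differ between temperatures. At 18 °C CG10581 was 6.27-fold higher (log2 2.65 ± 0.236 SE, limma adjusted p = 6.78e-09), CG6602 4.94-fold (2.30 ± 0.182, 1.07e-09), the predicted cuticle protein gene Cpr60D 3.71-fold (1.89 ± 0.180, 2.04e-08) and CG43117 3.47-fold (1.80 ± 0.164, 9.59e-09), each higher in 12 of 12 time-matched pairs. CG17931 was lower in all 12 pairs, at 0.355 times its HC25 level (log2 -1.49 ± 0.126 SE, adjusted p = 2.67e-09), and dhd, a thioredoxin gene of the female germline, was at 0.173 times (-2.53 ± 0.506, adjusted p = 0.00213). NPF, the neuropeptide F gene, fell to 0.425 times its HC25 level (-1.23 ± 0.216, higher in 1 of 12 pairs, adjusted p = 0.000585). In all, 711 genes passed, 512 higher and 199 lower at 18 °C, and 2120 had an unadjusted p below 0.05. The split was 553 higher and 525 lower after rescaling by the median ratio and 594 and 449 after quantile normalization. Without the HC25 library of ZT06 it was 393 higher and 371 lower (764 genes), and without the 3 libraries least like the others 483 and 492 (975 genes). Without the 4 HC18 libraries low in fmt 138 genes passed (71 higher and 67 lower), and 22 of the 63 named genes with a changed level still did.

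Other named genes that rose at 18 °C were CG13051 (3.79-fold), CG31954 (3.67-fold), Scp2, a calcium-binding protein gene (3.55-fold), CG18598 (2.63-fold), CG9338 (2.69-fold) and the heat shock gene Hsp70Ab (8.46-fold, higher in 10 of 12 pairs, limma adjusted p = 0.0115). Without the 4 HC18 libraries low in fmt, Hsp70Ab was 3.21-fold (adjusted p = 0.319) and CG9338 2.23-fold (adjusted p = 0.145), and neither passed. The others that fell were the lysozyme genes LysD (0.133 times) and LysB (0.145 times), the yolk protein genes Yp1 (0.256 times) and Yp3 (0.346 times), CG43798 (0.327 times), the mitochondrial gene mt:ND6 (0.356 times), Hr4 (0.383 times) and CG7518 (0.400 times). None of these 8 passed without the 4 libraries, with adjusted p of 0.123 for LysD, 0.202 for LysB, 0.300 for Yp1, 0.388 for Yp3, 0.0917 for CG43798, 0.244 for mt:ND6, 0.627 for Hr4 and 0.210 for CG7518; LysD was then at 0.146, LysB at 0.198, Yp1 at 0.432, Yp3 at 0.541, CG43798 at 0.317, mt:ND6 at 0.639, Hr4 at 0.704 and CG7518 at 0.514 times the HC25 level. Without the HC25 library of ZT06, LysD was at 0.242 and LysB at 0.292 times the HC25 level (adjusted p = 0.00821 and 0.00759), while Hr4 (adjusted p = 0.0843) and Yp3 (adjusted p = 0.0579) no longer passed. LysB and LysD had 17425 and 12029 TPM in the HC25 library of ZT06, but medians of only 0 and 0.43 TPM over the other 35 libraries. LysB, LysD and Hsp70Ab have near-identical copies, so their levels are uncertain. Pdf was 1.29-fold (log2 0.37 ± 0.167 SE, 9 of 12 pairs, adjusted p = 0.165) and Stip1 1.27-fold (0.35 ± 0.118, 11 of 12 pairs, adjusted p = 0.0651), and neither passed.

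Of the cytosolic ribosomal protein genes 47 of 76 rose and 0 fell (61 and 1 adjusted over the list alone), with RpL19 1.78-fold, RpL40 1.50-fold and RpS18 1.42-fold higher (higher in 10, 11 and 12 of 12 pairs). The list's median log2 difference was 0.42 (camera adjusted p = 2.1e-23; adjusted p = 0.777 with an estimated correlation; fry adjusted p = 0.00357). Of the proteasome genes 13 of 32 rose and 0 fell (17 and 0 adjusted over the list alone), with Prosbeta1 1.60-fold and Prosalpha2 1.38-fold higher and a list median of 0.31 (camera adjusted p = 5.71e-09; adjusted p = 0.777 with an estimated correlation; fry adjusted p = 0.0289). Of the chaperones and co-chaperones 10 of 30 rose and 1 fell (13 and 1 adjusted over the list alone), with the chaperonin subunits CCT5 1.66-fold and CCT7 1.55-fold higher and a list median of 0.28 (camera adjusted p = 4.75e-05; adjusted p = 0.777 with an estimated correlation; fry adjusted p = 0.0925). Without the 4 HC18 libraries low in fmt, 7 ribosomal protein genes, 0 proteasome genes and 1 chaperone gene passed, all higher, and camera still called these lists with medians of 0.32, 0.24 and 0.17 (adjusted p = 9.91e-23, 1.54e-08 and 0.000306). In insulin and TOR signalling 0 of 24 rose and 2 fell (0 and 2 adjusted over the list alone; 0 and 4 after rescaling), namely scyl (0.750 times) and chrb (0.744 times), and the list median was -0.15 (camera adjusted p = 0.0307; adjusted p = 0.777 with an estimated correlation; fry adjusted p = 0.305). Without the 4 libraries neither scyl (0.789 times, adjusted p = 0.193) nor chrb (0.748 times, 0.0883) passed, and neither did the list in camera (adjusted p = 0.0521).

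**Figure D4:**
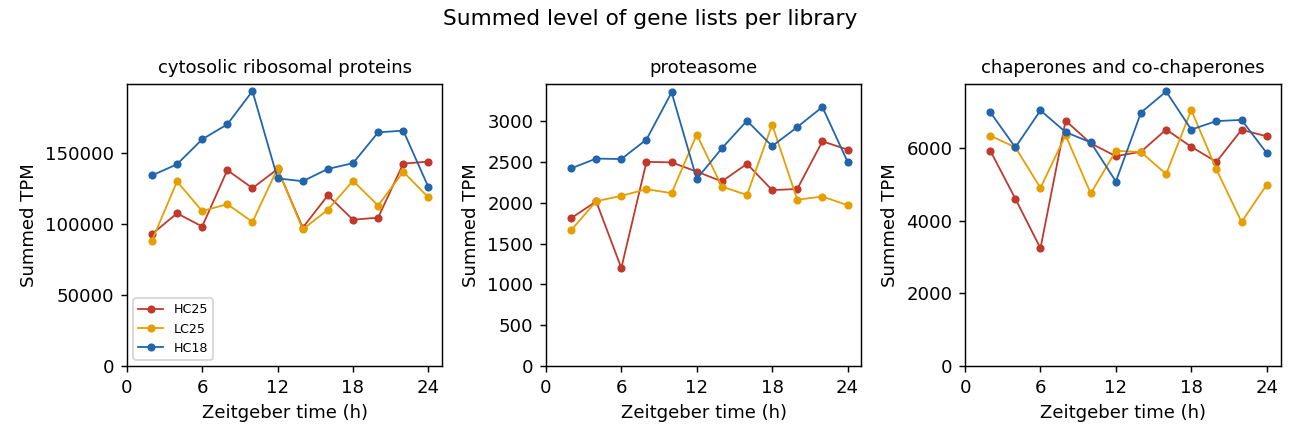
Summed TPM of the cytosolic ribosomal protein, proteasome and chaperone lists against zeitgeber time in hours, with 1 point per library and 1 line per condition. The highest ribosomal protein sum, 193833 TPM, was in the HC18 library of ZT10, which is among the 4 libraries low in fmt.

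In the core clock list 2 of 8 genes rose and 1 fell (2 and 2 adjusted over the list alone): cry was 1.91-fold higher (limma adjusted p = 0.00215; 1.76-fold and 0.0612 without the 4 libraries), per 1.42-fold higher (0.0469; 1.26-fold and 0.424 without the 4 libraries and 0.0832 without the HC25 library of ZT06), and Pdp1 was at 0.658 times its HC25 level (0.0173; 0.699 times and 0.0982 with log2 fmt as a covariate). Of the LNv markers and neuropeptides 1 of 8 rose, Pdfr (1.52-fold; 1.46-fold and adjusted p = 0.0993 without the 4 libraries), and 1 fell, NPF, which passed without them (1 and 1 adjusted over the list alone). In neuropeptide processing and release 6 of 18 rose and 0 fell (7 and 1 adjusted over the list alone), including 7B2, a convertase chaperone (1.55-fold; 1.34-fold and adjusted p = 0.141 without the 4 libraries), and svr, a carboxypeptidase (1.50-fold), and without the 4 libraries only svr passed. In oxidative stress defence 4 of 17 rose and 0 fell (6 and 0 adjusted over the list alone), led by the peroxiredoxin gene Prx5 (1.54-fold). Without the 4 libraries only Prx5 passed there (adjusted p = 0.0470), and Prx2 (1.24-fold, 0.328), Sod1 (1.20-fold, 0.343) and Trxr1 (1.27-fold, 0.359) did not; Sod1 (0.0739) and Trxr1 (0.0785) did not pass without the HC25 library of ZT06 either. The respiratory chain had 3 higher and 3 lower genes of 72 (3 and 3 adjusted over the list alone), among them UQCR-11 (0.672 times), the only one that passed without the 4 libraries; without the HC25 library of ZT06, 2 were higher and 5 lower. The unfolded protein response had 2 higher and 0 lower of 17 (3 and 1 adjusted over the list alone), ERp60 and Cnx99A, and neither passed without the 4 libraries (1.21-fold and 1.28-fold, adjusted p = 0.359 and 0.185). Single members passed in glycolysis (PyK, higher), the cold-induced genes (regucalcin, lower) and the activity-regulated genes (kay, lower), the same counts as adjusted over the list alone, and 0 in clock kinases, excitability, autophagy and antimicrobial peptides. Without the 4 libraries PyK (1.39-fold, adjusted p = 0.246), regucalcin (0.709 times, 0.139) and kay (0.637 times, 0.112) did not pass. As single transcripts regucalcin turned direction (log2 0.53). Without the HC25 library of ZT06 PyK did not pass (0.0563), and 1 clock kinase gene, 1 autophagy gene and 2 cold-induced genes were lower. None of these lists passed in camera.

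Markers of other cells also differed. Of the fat body markers 0 of 5 were higher and 2 lower (0 and 4 adjusted over the list alone), Yp1 and Yp3, with a list median of -1.23 (camera adjusted p = 0.00679; adjusted p = 0.777 with an estimated correlation; fry adjusted p = 0.117); the list did not pass without the 4 HC18 libraries low in fmt, and without the HC25 library of ZT06 1 member was lower. The HC25 library of ZT08 held the most fat body and glia markers of all 36, and without the 3 libraries least like the others the fat body list had adjusted p = 0.0626 in camera. Of the glia markers 1 of 8 fell, Indy (0.543 times; 1 adjusted over the list alone). Of the 3 haemocyte markers Pxn was higher (1.39-fold) and Nplp2 lower (0.327 times), against 1 higher and 2 lower adjusted over the list alone; without the 4 libraries neither passed, with Pxn at 1.21-fold (adjusted p = 0.258) and Nplp2 at 0.545 times (adjusted p = 0.414). Higher genes were toy (1.36-fold) and Fas2 (1.31-fold) of the 8 Kenyon cell genes (3 higher and 1 lower adjusted over the list alone), Ddc of the 8 monoaminergic genes (1.79-fold) and Dh44 of the 4 genes of other clock neurons (1.98-fold), each the only call also when adjusted over the list alone. Of these 4 genes only Dh44 passed without the 4 libraries (1.25-fold and adjusted p = 0.249 for toy, 1.22-fold and 0.262 for Fas2, 1.52-fold and 0.0553 for Ddc), and Fas2 did not pass without the HC25 library of ZT06 (0.0507). Of the photoreceptor, muscle and transmitter synthesis markers 0 passed, also adjusted over the list alone. None of these lists but the fat body list passed in camera.

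The authors' deposited table of rhythms over all 36 libraries gave a further view of the shared rhythm. Of 7724 genes in both, the cosine fit called 1961 and 1779 were called in the authors' deposited table, each at an adjusted p below 0.05, and 1510 were called by both (452 by independent lists, odds ratio 68.4), which is 84.9% of the authors' calls. Peaks lay within 3 h of each other for 73.2% of the shared calls, with a median absolute difference of 1.95 h. In the authors' deposited table per had a phase of ZT17.2, tim of ZT13.6 and vri of ZT14, with adjusted p of 3.05e-06, 7.39e-08 and 1.23e-07. Pdf had an adjusted p of 0.656 there and Stip1 of 0.00504.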

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

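The tests of the 4 HC18 libraries low in fmt, of scaling and of the HC25 library of ZT06 were chosen only after the results were seen. Transcripts of the Gal4 reporter, which the gene tests left out, varied 3.07-fold over the day in the 3 conditions (log2 amplitude 0.81 ± 0.0943 SE, n = 36 libraries, limma p = 1.02e-09), with a peak at ZT20.8 and a mean of 90.5 TPM. The mCD8GFP reporter, at a mean of 19663 TPM, had a fitted 1.43-fold range (limma p = 0.0966).

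The count of genes with another level at 18 °C moved with 4 HC18 libraries. Scaling as the whole cause is argued against: after rescaling by the median ratio 679 of the 711 called genes, or 95.5%, were still called in their direction. The number of libraries removed is argued against as the whole cause. Without the 4 libraries low in fmt 138 genes passed. Each of 70 removals of 4 of the other 8 HC18 libraries left between 203 and 1334. The 4 libraries low in fmt lie at ZT06, ZT08, ZT10 and ZT22, time points that the 70 removals left in place. At ZT06 and ZT08 the HC25 libraries paired with them also stood apart from the rest. A candidate explanation is another composition of the 4 HC18 libraries. Without them the called genes kept a median share of 0.813 of their fold change, below the 0.986 to 1.20 of the 70 other removals. Neither the count nor the share can separate this from the loss of these time points. Nor can they separate it from the loss of the pairs with the HC25 libraries that stood apart. Temperature stays open and untested for the rest, and the labels give no batch.

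The HC25 library of ZT06 held 52696 TPM of lysozyme transcripts and 7.68% of Pdf. Of the 9 lists of other cell types 2 exceeded 1.5 times their median over the other 35 libraries, the fat body (4.82 times) and glia lists (3.97 times), while 5 were at their lowest of the 36 libraries: photoreceptors (0.558 times), muscle (0.683 times), Kenyon cells (0.277 times), monoaminergic neurons (0.548 times) and transmitter synthesis (0.532 times). These ratios are of TPM shares, which the lysozyme and other transcripts high in this library lower. After rescaling by the median ratio photoreceptors stood at 0.931, monoaminergic neurons at 0.943 and Kenyon cells at 0.447 times their medians. Glia then stood at 7.14, haemocytes at 1.73 and other clock neurons at 1.60 times. A lower share of LNv cells that raised the other types alike is argued against only if the listed transcripts came from those types. If the sorted LNv cells supplied them, the lists could not decide this, and their origin was not tested. Of the 4 lists without genes that cycle in the sorted cells, 2 (muscle and transmitter synthesis) lay below 1.5 times their median by more than 2 SD of their log2 sums, also after rescaling by the median ratio (1.21 and 0.938 times), where the fat body list stood at 9.02 times. RNA from a further tissue or from the types that rose stays open and was not tested, and no biological explanation was tested, since 1 library stands for this time point and condition.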

How the results depend on the processing

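Fits without the HC25 library of ZT06, without the 3 libraries least like the others (HC25 ZT06, HC25 ZT08 and HC18 ZT24) and without the 4 HC18 libraries low in fmt, the fmt covariate, the authors' table at 25 °C and overlaps of conditions fitted alone were chosen after seeing the data. Of 4569 values of named genes under alternatives, for 313 results, 4179 kept direction and side of the threshold, 136 newly passed, 193 no longer passed and 61 turned direction. For per, tim, Clk, vri and Pdp1 all 290 rhythm values stayed past the threshold (largest adjusted p 0.00679). Unless said otherwise the cause was not tested. Depth is unknown, so its effect cannot be given.

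The level count at 18 °C, 711 (512 higher, 199 lower), was 1078 (553 and 525) after rescaling by the median ratio, 1043 (594 and 449) after quantile normalization, 1496 (835 and 661) with array weights, 1180 (938 and 242) without the library of each condition with fewest genes, 422 (299 and 123) with no time term, 764 (393 and 371) without HC25 ZT06, 975 (483 and 492) without the 3 libraries, 138 (71 and 67) without the 4 libraries and 237 (138 and 99) with the fmt covariate. The count on poorer food, 0, was 2 with array weights and 1 without the 3 libraries. The rhythm difference at 18 °C, 0, was 1 after rescaling by the median ratio, 1 after quantile normalization, 7 with array weights, 5 without HC25 ZT06 and 4 without the 3 libraries. Array weights gave 692 rhythmic genes in HC25, 827 in LC25 and 1165 in HC18. HC25 had 272 fitted alone, and HC18 had 270 without the 4 libraries and 313 as single transcripts. Other removals of 4 libraries were not run for the rhythm count, so the effect of fewer samples on the 270 is unknown. The rank test gave 46 in HC25, 53 in LC25 and 282 in HC18. Overlaps of conditions fitted alone were 196 (HC25 and LC25) and 215 (HC25 and HC18). The 5 lists called on poorer food became 0 with an estimated correlation, 0 in fry, 1 without HC25 ZT06 and 1 without the 3 libraries. The 5 called at 18 °C became 0 with an estimated correlation, 2 in fry and 3 without the 4 libraries. The overlap with the authors' deposited table was 2287 at unadjusted p and 786 with their table at 25 °C.

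Level differences at 18 °C (log2) that turned direction were, with array weights, VAChT -0.033, AttB -0.035, AstC -0.049, DAT -0.069, Dh31 0.042 and Mlc1 0.14. With the fmt covariate they were DAT -0.0068, Tm1 -0.033, Mlc1 0.031 and CNMa 0.38. After quantile normalization they were Tm1 -0.014 and VAChT -0.056, and after rescaling Tm1 -0.029 and VAChT -0.063. As single transcripts they were ND-20 -0.16 and regucalcin 0.53, both called genes, and Ald1 -0.42. Without HC25 ZT06 they were Tm1 -0.0062 and VAChT -0.018, and Stip1 on poorer food was -0.013. Without the 3 libraries they were AttB -0.052, VAChT -0.086, AstC -0.23, Tret1-1 0.041 and alrm 0.093, and Stip1 on poorer food was -0.0086. Without the 4 libraries they were Tm1 -0.064, DAT -0.14, Dh31 0.046, Mlc1 0.11 and CNMa 0.26. Without the libraries with fewest genes they were VAChT -0.12 and Dh31 0.093.

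Rhythms whose direction turned (a fitted phase moved by more than 6 h) had these log2 amplitudes. With array weights they were 0.13 for up over the 3 conditions and 0.18 for Pdf in HC25. After rescaling, crq had 0.0055, RpL15 0.062 and Pdf 0.079 over the 3 conditions. After quantile normalization crq had 0.012 over the 3 conditions. Pdf in HC18 then had an amplitude of 0. It is counted among the 61 values that turned direction, but a curve of amplitude 0 has no phase to turn. As single transcripts crq had 0.21. Pdf in HC25 had 0.19 without HC25 ZT06 and 0.26 without the 3 libraries. Rhythm differences that turned were, at 18 °C, Pdf 0.10 and cry 0.19 with array weights, cyc 0.057 with the covariate, Stip1 0.026 after quantile normalization and 0.024 after rescaling, tim 0.64 as single transcripts, Pdf 0.11 without HC25 ZT06 and 0.21 without the 3 libraries, and Stip1 0.11 and cyc 0.15 without the 4 libraries. On poorer food they were per 0.16 with array weights, vri 0.075 after quantile normalization and 0.11 after rescaling, per 0.19 without HC25 ZT06, Pdp1 0.15, per 0.18 and Pdf 0.24 without the 3 libraries, and vri 0.49 without the libraries with fewest genes.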

Other observations

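The list of lysozymes was chosen only after the data were seen. Several transcripts known from other neurons cycled in the sorted cells. Of the monoaminergic genes 4 of 8 were rhythmic over the 3 conditions (4 adjusted over the list alone): Tdc2, a tyrosine decarboxylase, varied 6.38-fold with a peak at ZT8.36 (limma adjusted p = 1.55e-10) and Ddc, dopa decarboxylase, 3.92-fold with a peak at ZT7.17 (adjusted p = 7.96e-11), while Tbh varied 2.44-fold and DAT 1.76-fold. Of the genes of other clock neurons 2 of 4 were rhythmic (2 adjusted over the list alone), Dh31 and the diuretic hormone gene Dh44 (4.29-fold, ZT15.7, adjusted p = 1.13e-06). Of the Kenyon cell genes 2 of 8 were rhythmic (2 adjusted over the list alone), toy (1.66-fold) and sNPF. The permutation test of the median F gave an adjusted p of 0.0161, the smallest it can give, for these 3 lists and for transmitter synthesis of other neurons, of which 0 of 4 genes were rhythmic (2 adjusted over the list alone). Of these transmitter genes 2 passed without the HC25 library of ZT06, 2 without the 3 libraries least like the others and 1 without the 4 HC18 libraries low in fmt.

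Among markers of cells that are not LNv neurons, 2 of 8 glia markers were rhythmic (2 adjusted over the list alone), Tret1-1 (4.41-fold) and Indy (1.78-fold). Tret1-1 is also counted in the glycolysis and trehalose list. Of the photoreceptor markers 1 of 7 was rhythmic (1 adjusted over the list alone), rdgB (2.56-fold, ZT11.4). Over the 3 conditions 0 of 5 fat body, 0 of 3 haemocyte and 0 of 5 muscle markers were rhythmic in limma, also adjusted over the list alone. In LC25 alone 1 of 5 muscle markers was rhythmic. The permutation test of the shared rhythm gave adjusted p of 0.206 for glia, 0.328 for photoreceptors, 0.208 for the fat body, 0.526 for haemocytes and 0.71 for muscle. Within single conditions only glia in HC25 passed it among these lists (adjusted p = 0.0429). There 1 of 8 glia markers was rhythmic, 0 without the HC25 library of ZT06 and 1 without the 3 libraries least like the others. The HC25 libraries of ZT06 and ZT08 held 973 and 1983 TPM of glia markers, against a median of 247 TPM. The permutation test was not repeated without these libraries. Of the 4 lysozymes measured 0 were higher and 2 lower at 18 °C (0 lower without the 4 HC18 libraries low in fmt), with a median log2 difference of -2.19, and the median on poorer food was -1.97 with 0 called. Without the HC25 library of ZT06, which held 52696 TPM of lysozyme transcripts, the medians were -1.17 with 2 lower and -0.93 with 0 called. Over the other 35 libraries the median level was 0.89 TPM for LysP, 0.43 for LysD, 0 for LysB and 0 for LysE.

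The HC25 library of ZT08 held 1983 TPM of glia markers, 8.01 times the median library, and 260 TPM of fat body markers, 10.97 times the median. The LC25 library of ZT18 held 1194 TPM of photoreceptor markers, 5.35 times the median.

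Other orders of the time points were drawn 100 times, the real one included, and they argue against chance for the rhythm counts as far as 100 draws can show. For HC25 1 order gave as many as the real 731 genes (highest other 6), for LC25 1 gave as many as 531 (highest other 2), for HC18 1 as many as 477 (highest other 16) and over the 3 conditions 1 as many as 2065 (highest other 1). Swaps of the conditions within time points were also drawn 100 times. For the level at 18 °C 1 swap gave as many as the real 711 genes (highest other 36), which argues against chance to the same extent. The swaps cannot tell temperature from another difference between the libraries of the conditions. For the counts of 0 all 100 gave as many, as any swap must, which says nothing of chance: the level on poorer food (highest other 1), the rhythm difference on poorer food (highest other 2) and the rhythm difference at 18 °C (highest other 324). A swap with 324 genes points to a structure of the samples, and which libraries it rests on was not examined.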
